A study of Mus musculus with 16 samples.

How the data were processed

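Methylated RNA immunoprecipitation sequencing (MeRIP-seq) was used to map N6-methyladenosine (m6A), a methyl mark on adenosines of RNA, in the livers of male mice. The labels name 16 libraries from 8 mice, 4 lean C57BL/6 mice and 4 db/db mice, which lack a working leptin receptor and become obese and diabetic. Each mouse gave 1 immunoprecipitated library and 1 input library. Groups and mouse numbers were taken from the sample titles.

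The deposited data were 8 lists of peaks labelled as mRNA peaks, 1 per mouse, which also name some small RNA genes, such as Snord88a. Each list was assigned to the immunoprecipitated library whose title holds the name of its sheet. Peaks were named in the style of MACS, per the file headers, and mice were not pooled. Per the submitters' processing notes, reads were handled with cutadapt 1.9.3 and HISAT2 2.0.4, and the build was mm10. The version of the peak caller and its use of the input libraries were not given in the sources used here. The fold enrichment of a peak is a ratio that the authors deposited, and it is relative to the background of its own list. The score of a peak in the deposited lists is -10 times the log10 of its p-value. The smallest score listed was 50, a p-value of 1e-05, and the smallest fold was 2.35. The length of a peak in bases was the third deposited value, and the shortest peak held 1 base. A further 8 columns, 1 per list, were not used. The 8 input libraries were not analysed here. With no read counts, sequencing depth was unknown, and a missing peak can mean a lack of methylation, low expression of the gene or too few reads. Fold enrichment and score were used to describe, rank or filter peaks within a list and to pick out those over 100-fold, by each list's own fold. The other comparisons between mice rested on the presence, position and length of peaks.

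Peaks of the 8 lists were merged into regions where they shared at least 1 base within a gene. Starts were converted to count from 1. Gene names and IDs were those of the lists. Of 8284 gene names, 8076 had an ID in the RefSeq annotation of GRCm38.p6, which has the coordinates of mm10, and 98.3% of the 27637 peaks with such an ID had their midpoint inside the named gene. That annotation gave gene bounds without exons or strand, and no genome sequence was used. The planned shares of peaks by transcript location and of peaks with a DRACH motif were therefore not analysed here. Small RNA genes of up to 400 bases were taken from the same annotation, and a peak overlapped 1 if they shared at least 1 base.

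Values per mouse were compared with an exact two-sided permutation test over the 70 assignments of 8 mice to 4 and 4, whose smallest p is 0.0286. Peak sets were compared by the Jaccard index, the bases shared by a pair of lists over the bases covered by either, by the share of peaks with at least 50% of their bases in the other list and by the Jaccard index of gene names, each with a one-sided exact test over the 35 splits of the 8 mice. Regions and genes with a peak in all mice of one genotype and none of the other were counted and set against the same 35 splits. Each region and gene also had a two-sided Fisher exact test with Benjamini-Hochberg adjustment, which at 4 against 4 mice cannot give a p below 0.0286. For 18 gene lists with 359 genes, fixed before the data were examined, the share of members with a peak was computed per mouse over members with a peak in at least 1 mouse. List members among genes seen in one genotype only were tested with Fisher's exact test. In all, 198 list genes had a peak, 1 of them matched through its gene ID.

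Genes to name were also chosen by a rule fixed before the data were examined. The rule takes Psmd14, Mettl3 and Acss3. It takes up to 12 genes per direction with a peak in all mice of one genotype only, ranked by the mean within-list percentile of their best fold, without predicted genes. From each list it takes members seen in one genotype only or, failing those, up to 2 per direction with the largest difference in number of mice. Last, it takes the 5 genes of highest mean percentile among those with a peak in all 8 mice. Other genes are said to have been chosen after their values were seen. Some genes that the rule takes are not reported here.

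The functions were tested on simulated data. Among 8284 simulated genes, 200 were given a peak in 90% of mice of one genotype and 2% of the other, and the count of genes seen in all mice of one genotype only held 63% of them. Of the 148 genes so counted, 22 had not been given such a difference. With no gene given such a difference, the count by genotype was 22 and the highest other split gave 45. Alternatives fixed at the same time were a stricter fold of 4.7, equal list lengths of 2475 peaks, other definitions of overlap, presence and background, a replicate block and leaving out each mouse. Equal length kept the peaks of highest fold in each list. A p of at most 1e-10 and removal of peaks at small RNA genes were added after seeing the data. Python 3.11.15, numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9 were used.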

Results

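The deposited lists held 28297 m6A peaks of 8 mouse livers, 4 from lean mice and 4 from db/db mice. The series concerned fatty liver disease and RPN11, a deubiquitylating enzyme of the proteasome encoded by Psmd14. The comparison of the genotypes asks which liver transcripts carry m6A in obese, diabetic mice and which in lean mice. Lists held between 2475 and 4807 peaks, in 2018 to 3444 genes. The median fold enrichment of a list, the authors' own value, lay between 9.69 and 13.0. Sequencing depth was unknown, and the labels mark the mice as separate samples of each genotype.

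Peaks were found in 8284 genes, and 298 of these had a peak in every mouse. Among the genes with a peak in all 8 mice were Fasn, the fatty acid synthase, Plin2 and Plin4, which coat lipid droplets, and Ythdc1 and Zc3h13, a reader of m6A and a subunit of its writer complex. These 5 genes were chosen after their values were seen. In contrast, 3186 genes, or 38.5%, had a peak in 1 mouse only.

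Livers of db/db mice had 3882 ± 848 peaks (SD, n = 4) and those of lean mice 3192 ± 833 (SD, n = 4), a difference within the spread between mice (exact permutation test, two-sided, p = 0.314). The genes with a peak numbered 2928 ± 458 in db/db mice and 2530.0 ± 630 in lean mice (SD, n = 4 each, exact permutation p = 0.371). Peaks covered 393 ± 122 kb in db/db and 316 ± 105 kb in lean mice (SD, n = 4 each, exact permutation p = 0.286). The Jaccard index of bases averaged 17.0% over the 12 pairs of mice of one genotype and 16.5% over the 16 pairs of different genotypes (one-sided exact test over 35 splits, p = 0.143). Lean pairs averaged 17.8% and db/db pairs 16.3%, so that db/db pairs lay below the pairs of different genotypes. When similarity was measured as the share of peaks with at least 50% of their bases in the other list, the means were 23.9% and 23.0% (exact p = 0.0286, the smallest the splits can give). By that measure lean pairs averaged 26.2% and db/db pairs 21.6%, so that only lean pairs lay above the pairs of different genotypes. By the Jaccard index of gene names the means were 28.2% within and 27.5% between genotypes (exact p = 0.0857), and there db/db pairs, at 28.7%, lay above lean pairs, at 27.8%. Without lean mouse 4, the difference in the Jaccard index of bases was -0.0990 percentage points.

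**Figure D1:**
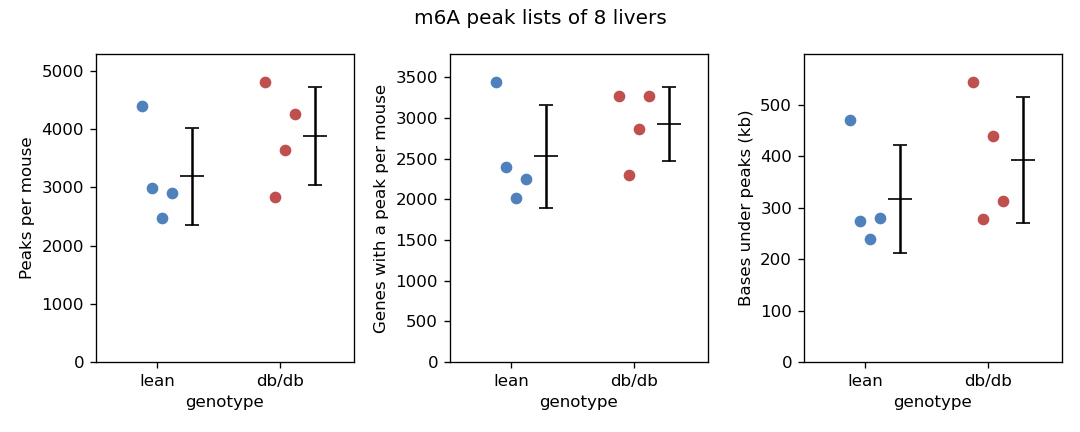
Number of peaks, number of genes with a peak and kilobases under peaks, 1 point per mouse, for 4 lean (blue) and 4 db/db (red) livers, with the mean and SD in black. The ranges of the genotypes overlap in each panel, with 2475 to 4394 peaks in lean and 2831 to 4807 in db/db mice.

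The genes of the study's own question had few peaks. Psmd14 (gene ID 59029) had a peak in 1 lean mouse and no db/db mouse, at chromosome 2, 61760637 to 61760689 (mm10), with a fold of 9.23. Mettl3 (gene ID 56335), the catalytic subunit of the m6A writer, had a peak in 1 db/db mouse and no lean mouse, at chromosome 14, 52304944 to 52305025, with a fold of 14.5. Acss3, an acyl-CoA synthetase of mitochondria, had no listed peak. Fisher's exact p was 1 for both Psmd14 and Mettl3.

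Regions of Cyp4a32, Selenbp2 and Fam83f carried a peak in all 4 db/db mice and no lean mouse, and regions of Klrc1, Klrc2, Hamp2, Dpys, Cyp2c40 and Selenbp1 in all 4 lean mice and no db/db mouse. Cyp4a32 belongs to a family of fatty acid hydroxylases, and its region lay at chromosome 4, 115600938 to 115601163, with a median fold of 68.3. Hamp2 encodes a hepcidin, Dpys an enzyme of pyrimidine breakdown, and Klrc1 and Klrc2 are receptors of natural killer cells. The regions of Klrc1 and Klrc2 were each 62 bases long, with the same lowest fold, 18.8, and the same median fold, 24.3. That of Klrc2, at chromosome 6, 129649226 to 129649287, lay outside the annotated bounds of the gene, which start at 129649602. The Klrc1 and Klrc2 regions may therefore not be separate results. The Hamp2 region lay at chromosome 7, 30924049 to 30924181, and that of Dpys at chromosome 15, 39857280 to 39857470, with median folds of 9.73 and 7.87. Selenbp1 and Selenbp2, genes of selenium-binding proteins, went opposite ways. The Selenbp1 region was at chromosome 3, 94944406 to 94944757, and the Selenbp2 region at 94704054 to 94704399 of the same chromosome. Where members of a gene family share sequence, which was not tested here, reads of one gene can be placed in another. The values of such genes are uncertain for that reason. Of the genes named here, Cyp4a32, Cyp2c40, Klrc1, Klrc2, Selenbp1 and Selenbp2 had a neighbour within 1 Mb whose symbol has the same stem.

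In all, 13 of 17936 regions had a peak in all db/db mice only and 17 in all lean mice only. Their total of 30 was the highest of the 35 splits of the 8 mice, with 25 for the next. That next split set mice 1 and 3 of both genotypes against mice 2 and 4 of both. Of the 30 regions, 17 lay in genes that had peaks elsewhere in mice of the other genotype, among them Tnrc18, Ahdc1, Tshz1 and Scrib, chosen after their values were seen. No region passed the adjusted threshold in Fisher's exact test, the smallest adjusted p being 1. The smallest possible p of 0.0286 put that threshold out of reach for 30 of 17936 regions. The 30 regions with an unadjusted p under 0.05 were these same regions. Without db/db mouse 1, db/db mouse 2, lean mouse 1 or lean mouse 2, another split gave a total at least as large, and with lean mouse 2 left out 3 of 35 splits did so.

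Counted by gene, 17 genes had a peak in all db/db mice and no lean mouse, and 11 in all lean mice and no db/db mouse. Besides those above, the db/db genes included Dll4, a Notch ligand, Smc3, a subunit of cohesin, the transcription factor gene Sox4, Arid1a, a subunit of a chromatin remodelling complex, and Bahcc1, Ccdc85c, Syne3, Spns1 and Adam11. Of the lean genes, Map2k4, a kinase of stress signalling, had its peaks in 4 different regions, 1 mouse in each. Among the db/db genes, Dll4, Smc3, Syne3, Spns1 and Arid1a had no region shared by more than 2 mice, and Sox4, Bahcc1 and Adam11 had none shared by any. The total of 28 genes was reached or passed by 5 of the 35 splits, the highest other split giving 39 and the median other split 20. No gene passed the adjusted threshold in Fisher's exact test, and the smallest possible p of 0.0286 put it out of reach for 28 of 8284 genes. The 28 genes with an unadjusted p under 0.05 were these same genes. With lists of equal length the genotypes gave 30 genes and the highest other split 22. The balance between the genotypes then turned, with 11 db/db genes and 19 lean genes.

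**Figure D2:**
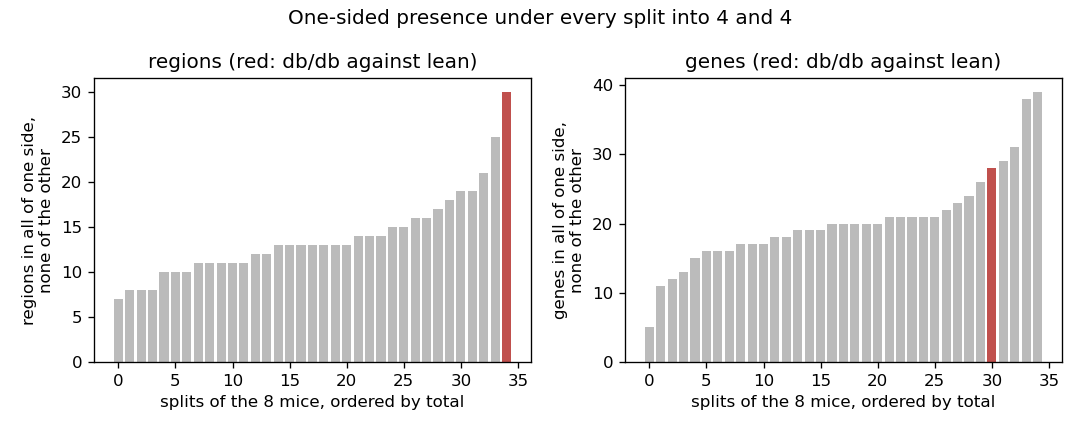
Number of regions (left) and genes (right) with a peak in all 4 mice of one side and none of the other, 1 bar for each of the 35 splits of the 8 mice, ordered by total. The red bar is the split by genotype, at 30 regions, above all others, and at 28 genes, below the highest other split of 39.

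Among genes of lipid metabolism, Acss2, which makes acetyl-CoA from acetate, and Scarb1, a receptor for high-density lipoprotein, each had a peak in 1 db/db mouse and 4 lean mice (Fisher's exact p = 0.143 each). Their regions were at chromosome 2, 155518055 to 155518173, and chromosome 5, 125340768 to 125341050. In the other direction Lpin1 and Plin3 each had a peak in 2 db/db mice and no lean mouse. Shares of a list are taken over its members with a peak in any mouse. For lipogenesis the share was 38.3% ± 18.4 in db/db and 40% ± 12.2 in lean mice. For lipid uptake and lipid droplets they were 40.4% ± 14.6 and 36.5% ± 9.68. For fatty acid oxidation and ketogenesis they were 26.6% ± 13.9 and 37.5% ± 11.4, with Hadhb in 0 db/db and 2 lean mice and Ppargc1a, a coactivator of oxidative genes, in 1 and 3. For cholesterol and bile acid metabolism they were 25% ± 8.39 and 33.3% ± 9.43 (SD, n = 4 per genotype throughout). With lists of equal length the difference for lipid droplets, db/db minus lean, turned to -7.69 percentage points, and those for lipogenesis and for cholesterol and bile acids grew to -5 and -15 (for the last, 10% against 25%, exact permutation p = 0.0857). The db/db lists were longer on average (3882 against 3192 peaks), so that equal length took more peaks from them. The share over all genes at equal length is not given here.

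Genes of glucose metabolism and insulin signalling had a peak in 38.2% ± 14 of members in db/db and 29.4% ± 15.2 in lean mice, with Tcf7l2 in 3 db/db mice and 1 lean mouse. The difference, 8.82 percentage points, was 2.94 without lean mouse 4 and 15.7 without db/db mouse 2, and 4.41 with lists of equal length. Clock genes had 33.9% ± 15.8 and 21.4% ± 13.0, with Cry2 and Dbp each in 2 db/db mice and no lean mouse. Proteasome and deubiquitylating enzymes had 32.1% ± 17.0 and 23.2% ± 8.99, with Psmc1 and Usp14 each in 2 and 0 mice. Stress response genes had 40% ± 8.16 and 32.5% ± 25, with Ddit4 in 2 and 0 mice, and a difference of 7.5 percentage points that rose to 20 without lean mouse 1. The m6A writers, erasers and readers had 40% ± 0 and 38.8% ± 12.5, with the eraser Alkbh5 in 2 db/db mice and the reader Ythdf2 in 2 lean mice, each in no mouse of the other genotype. No region of Tcf7l2, Cry2, Usp14, Ddit4, Alkbh5 or Ythdf2 had a peak in more than 1 mouse. Genes of propionyl-CoA and branched-chain amino acid metabolism had 32.7% ± 17.1 and 40.4% ± 13.1, and with lists of equal length 5.77% and 25%, a difference of -19.2 percentage points (exact permutation p = 0.0286, adjusted p = 0.514). The study's 3 genes, of which 2 had a peak, had 12.5% ± 25 in both genotypes. With lists of equal length, the difference (db/db minus lean) turned to -1.79 percentage points for the clock, -8.93 for the proteasome list and -1.25 for the m6A factors.

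Among cell type markers, Kupffer cell and macrophage markers had a peak in 37.5% of members in both genotypes (SD 14.4 and 10.8; a difference of -10.4 percentage points, db/db minus lean, with lists of equal length), with Adgre1 in 1 db/db mouse and 3 lean mice. Stellate cell and fibroblast markers had 45.8% ± 19.8 in db/db and 33.3% ± 13.6 in lean mice, with Col1a2 and Ecm1 each in 2 and 0, and with lists of equal length the difference turned to -2.08 percentage points. No region of Col1a2 or Ecm1 had a peak in more than 1 mouse. Sinusoidal endothelial markers had 41.1% ± 6.84 and 37.5% ± 6.84. Hepatocyte markers had 28.1% in both genotypes (SD 6.25 and 12.0), with Hnf4a in 3 db/db mice and 1 lean mouse and Ttr in 0 and 2. Cholangiocyte markers had 31.3% ± 12.5 in both genotypes, and a difference of -12.5 percentage points with lists of equal length. Of the lymphocyte and neutrophil markers only 2 had any peak, and of the adipocyte markers 1, with shares of 25% and 50% in both genotypes.

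None of the 18 lists passed the threshold in the exact permutation test (smallest unadjusted p = 0.343, every adjusted p = 1), and 0 had an unadjusted p under 0.05. Over all 8284 genes the share was 35.3% ± 5.53 in db/db and 30.5% ± 7.60 in lean mice (SD, n = 4 each, exact permutation p = 0.371). Relative to that share, cholesterol and bile acid metabolism was 13.1 percentage points lower in db/db mice (a difference of -13.1, exact permutation p = 0.0286, adjusted p = 0.514). Within the lists, 0 genes passed Fisher's exact test adjusted over the list alone, and 0 adjusted over all genes. Only a gene with a peak in all 4 mice of one genotype and none of the other can reach an unadjusted p under 0.05 there. No list held such a gene, and since at most 0.041 members per list were expected by chance, enrichment could not be assessed.

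**Figure D3:**
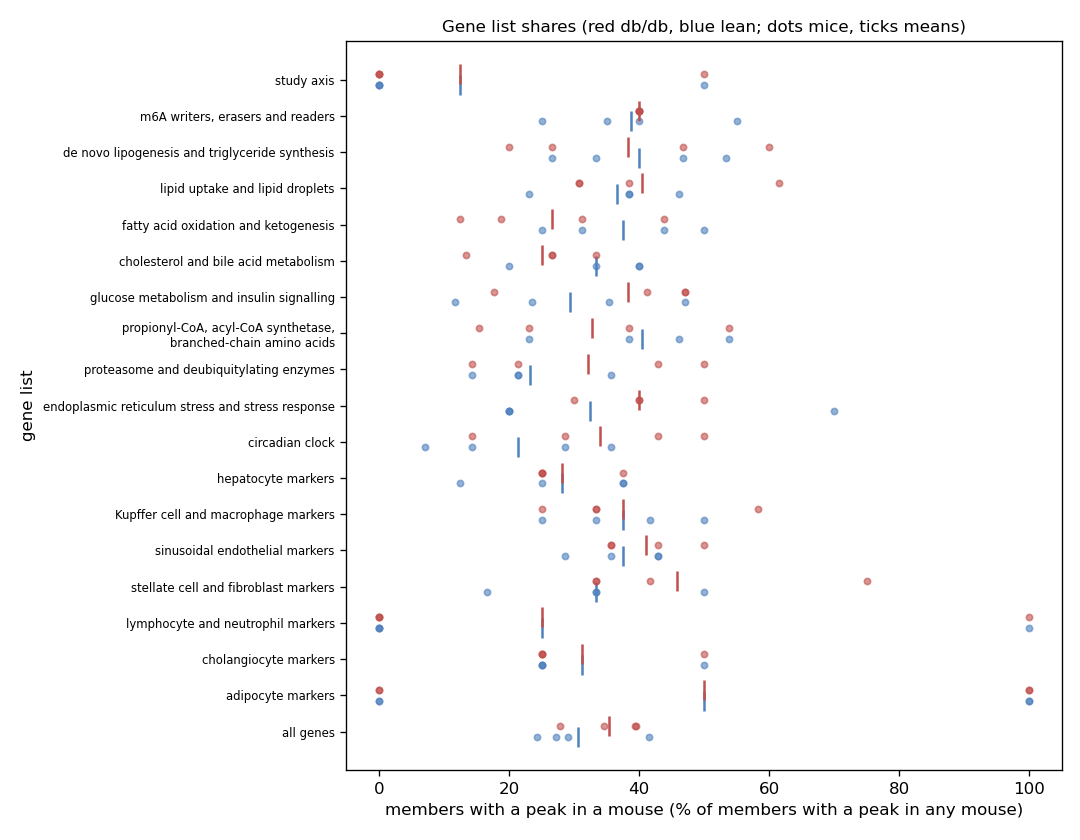
Share of each list's members with a peak (x axis, % of members with a peak in any mouse), 1 dot per mouse and a tick for the mean, for db/db (red) and lean (blue) livers, with all genes in the last line. The genotypes overlap in every list, and lists of which only 1 or 2 members had a peak step between few values.

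Among genes with a peak in all 8 mice, Lars2, Oprm1, AA474408, Dnm3os and Mup6 ranked highest by the mean within-list percentile of their best fold. Median folds over the mice were 14898 for Lars2 and 10505 for Oprm1. The regions of Lars2 and Oprm1 with a peak in all 8 mice overlapped no annotated small RNA gene. What gave folds of this size there was not tested. The Dnm3os region, at chromosome 1, 162217823 to 162217927, overlapped the microRNA gene Mir199a-2 and had a median fold of 7252. Mup6 belongs to the large family of major urinary protein genes. Between 43 and 85 peaks per mouse had over 100-fold enrichment, 58.5 ± 18.3 in db/db and 66 ± 10.2 in lean mice (SD, n = 4 each, exact permutation p = 0.571). Of these, 29.4% to 51.9% per mouse overlapped an annotated small RNA gene, against 0.360% to 0.833% of the other peaks. The number of peaks over small RNA genes was 44 ± 4 in db/db and 45 ± 2.31 in lean mice (SD, n = 4 each, exact permutation p = 0.743).

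**Figure D4:**
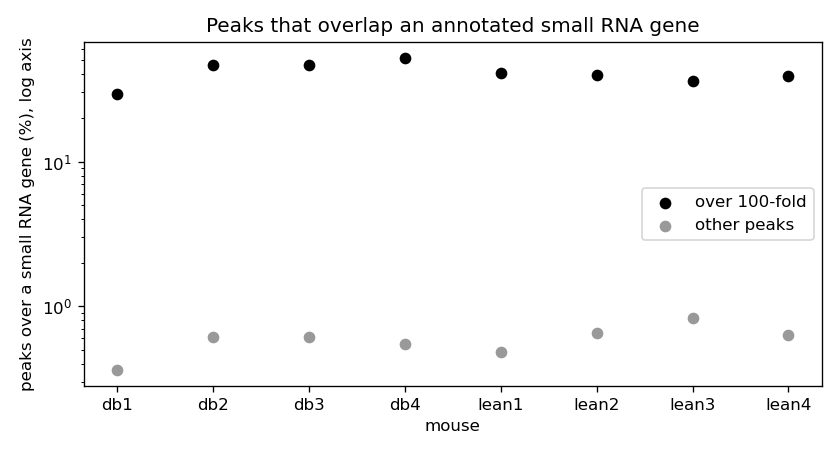
Share of peaks that overlap an annotated small RNA gene (log axis, %) in each mouse, for peaks of over 100-fold enrichment (black) and the other peaks (grey). The black points lie between 29.4% and 51.9% and the grey points between 0.360% and 0.833%.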

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

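The counts over splits, for regions and genes, and the equal list lengths were fixed before the data were examined. What the split count for genes and the equal lengths would show under each explanation was written after their results were seen. The tests of linked segments, paralogs, small RNA genes and numbers of peaks over 100-fold were chosen after seeing the data.

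In 10 of 54 groups of 4 mice, 1 mouse lay far from the rest. Chance gives about 1 in 20 for continuous values, but in 9 of these groups the other 3 mice had equal values, so that no excess over chance is shown. In lean mouse 1, 82.2% of genes with a peak also had 1 in another mouse, against 88.3% or more in the other lean mice. The share was as low in db/db mice 1 and 4, at 82.0% and 81.4%. These and lean mouse 1 had the most genes with a peak (3267, 3276 and 3444). In db/db mouse 4, 50 peaks overlapped small RNA genes, against 42 in each of the other db/db mice. Among the lists, with shares over members that had a peak in any mouse, lean mouse 1 had a peak in 70% of stress response genes, against 20% in each of the other lean mice, and db/db mouse 2 in 37.5% of hepatocyte markers, against 25%. The other 6 concerned lists of which 4 members or fewer had a peak. The study's own genes stood at 50% in db/db mouse 1 and in lean mouse 1, against 0 elsewhere. Lymphocyte and neutrophil markers stood at 100% in db/db mouse 4 and in lean mouse 1, against 0, and cholangiocyte markers at 50% in db/db mouse 1 and in lean mouse 4, against 25%.

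The 30 regions with a peak in one genotype only exceeded every other split, the highest of which gave 25. Thus 1 of 35 splits, the real one, was as large, the least the splits can give. That argues against chance at the 5% level with all 8 mice. The level was not reached without db/db mouse 1, db/db mouse 2 or lean mouse 1, where 2 of 35 splits were as large. Without lean mouse 2, 3 of 35 were. Other comparisons over the same splits were not adjusted for, and the count of genes fell short of this level. Longer lists in some mice are argued against, since with lists of equal length the total was 26 against 20 for the highest other split, and again 1 of 35 splits was as large. The strain label of the db/db mice names the mutation alone, so that strain variants in linked segments stay open. Lepr, the leptin receptor gene, lies on chromosome 4, at 101717137 to 101815352. On that chromosome lay 4 of the 30 regions, those of Cyp4a32, Cyp4a31, Acnat2 and Ahdc1. Whether this exceeds chance was not tested. Of the 30 regions, 11 lay within 5 Mb of another of them in another gene, against a median of 5 in 10000 draws from the 484 regions with a peak in 4 mice (permutation p = 0.03), but with neighbours within 1 Mb left out, a condition added after that count was seen, 3 did, against 4 (permutation p = 0.579). Regions within 1 Mb of each other, such as those of Klrc1 and Klrc2 or of Gm3776 and Gm10639, made up the difference. Whether such neighbours share sequence was not tested. Strain variants, reads shared between neighbours and an effect of genotype on m6A or expression therefore cannot be told apart.

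For the 28 genes with a peak in one genotype only, chance cannot be excluded, since 5 of 35 splits gave as many and the highest other split gave 39. With lists of equal length the total was 30 against 22 for the highest other split, and 1 of 35 splits was as large. This argues against longer lists in some mice as the source of the total, but not of its parts. The db/db genes went from 17 to 11 and the lean genes from 11 to 19, so the count in each direction moved with list length. Reads shared between clustered paralogs stay open. Of the 27 of these genes with an ID in the annotation, 22.2% had a neighbour of the same symbol stem within 1 Mb. Among all 8076 genes with a peak and such an ID, 11.6% did (odds ratio 2.20, Fisher's exact p = 0.119).

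Peaks of over 100-fold enrichment lay over annotated small RNA genes at least 43.2 times as often as other peaks in every mouse, which is consistent with small RNAs as a source of part of them. Reads shared between clustered paralogs stay open for the rest, since in 7 of 8 mice a higher share of the remaining peaks lay in genes with a neighbour of the same stem. The excess was slight in db/db mice 3 and 4, with 3 of 22 peaks each (13.6% against 11.8% and 10.7% of other peaks). In db/db mouse 2 the share was lower (11.1% against 12.3%). In db/db mouse 1 and the lean mice it was 21.4% to 41.8%. The genotype stays open too, as the numbers per mouse did not settle a difference (exact permutation p = 0.571). The difference, db/db minus lean, was -7.5 peaks, and -16.3 to -2.33 with 1 mouse left out.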

How the results depend on the processing

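The p limit of 1e-10 and the removal of small RNA peaks were chosen after seeing the data. Differences in peaks, genes with a peak and bases under peaks kept their direction and stayed short of the threshold under every alternative run, but their size moved. The difference in peaks ranged from 382 without db/db mouse 1 and 451 without lean mouse 3 to 1041 without db/db mouse 2 and 1091 without lean mouse 1. For genes it ranged from 228 without lean mouse 3 to 607 without db/db mouse 2 and 703 without lean mouse 1. For bases it ranged from 26.6 kb without db/db mouse 1 to 116 kb without db/db mouse 2 and 128 kb without lean mouse 1. At a p of at most 1e-10 the differences were 192.5 peaks, 154.5 genes and 34.4 kb. The same numbers do not pair the mice, since deviations of same-numbered mice correlated at -0.0280 to 0.00877 and 1 of the 4 db/db mice correlated best with its own number. With the replicate block the difference stayed at 690.3 peaks (exact sign-flip p = 0.25), and no call changed, in a test of 16 sign assignments that cannot reach the threshold. Depth is unknown and limits every absence of a peak. The planned location shares and DRACH motif share were not run, with their alternatives, and equal list length gives no value for the number of peaks, genes or bases.

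Similarity within genotypes, over lean and db/db pairs, exceeded that between them by 0.892 percentage points when peaks had to share 50% of their bases, past the threshold, although db/db pairs lay below pairs of different genotypes. The difference in the Jaccard index of bases, 0.525 with all mice, ranged from -0.0990 without lean mouse 4 to 1.07 without db/db mouse 2. For gene names it was 0.698. Causes were not tested. With presence in at least 3 of 4 mice, 202 genes, 142 db/db and 60 lean, were seen in one genotype only, a looser rule by construction, and 5 of 35 splits gave as many. Without predicted genes the lean genes numbered 7. With equal list lengths the db/db genes numbered 11 and the lean genes 19, because longer lists lost more peaks. At a p of at most 1e-10 there were 12 regions (5 db/db, 7 lean) and 10 genes (3 db/db, 7 lean).

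Leaving out 1 mouse asks for presence in fewer mice and so raises the counts. Regions numbered 47 to 56, 14 to 33 for db/db and 23 to 38 for lean mice. Genes numbered 49 to 74, 27 to 60 for db/db and 14 to 31 for lean mice. Of 35 splits, 1 to 3 gave as many regions and 3 to 21 as many genes.

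No list passed the threshold under any of these alternatives (adjusted p 0.514 to 1), but the sign of several differences (db/db minus lean, percentage points) turned, among them the 12.5 of the clock and of stellate cells. Relative to all genes it was -3.56 for m6A factors, -0.961 for lipid droplets and -1.24 for endothelial markers. With equal list lengths it was -1.25 for m6A factors, -7.69 for lipid droplets, -8.93 for the proteasome, -1.79 for the clock and -2.08 for stellate cells. At a p of at most 1e-10 it was 3.33 for lipogenesis, -5.77 for lipid droplets and 1.56 for fatty acid oxidation. Without 1 mouse it ranged from -3.33 to 6.67 for m6A factors, -8.89 to 4.44 for lipogenesis and -3.21 to 7.05 for lipid droplets. Other nonzero differences kept their sign, at -16.7 to -6.25 for fatty acid oxidation, -12.8 to -4.44 for cholesterol, -14.7 to -1.92 for propionyl-CoA, 2.94 to 15.7 for glucose, 2.98 to 14.9 for the proteasome, 3.33 to 20 for stress, 7.14 to 19.0 for the clock, 0.595 to 5.36 for endothelial and 2.78 to 18.1 for stellate cells.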

Other observations

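Small RNA genes under a peak often had 1 in every mouse. Of 64 small RNA genes under a peak, 34 had 1 in all 8 mice, namely 11 microRNA genes, 19 small nucleolar RNA genes and 4 others, whereas 3.6% of the 8284 gene names in the lists did. Mir21a, a microRNA within the peaks named for Vmp1, had a median fold of 1329, and Mir27b, under the name 2010111I01Rik, had 1191. Snord45c lay under the peak named for Rabggtb, with a median fold of 724, and the histone-processing RNA gene Rnu7 under that of Grcc10, with 311. No small RNA gene had a peak in all mice of one genotype and none of the other. These genes were chosen after their values were seen.

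Of the 298 genes with a peak in all 8 mice, the 115 with a pathway in the deposited lists were set against the 2971 of 8284 genes that had one. Of 253 pathways with at least 10 genes, 0 passed the adjusted threshold in Fisher's exact test and 12 had an unadjusted p under 0.05. The lowest p was for the cell cycle, with 7 genes where 2.55 were expected (Fisher's exact p = 0.0127, adjusted p = 1).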
